A study of Homo sapiens with 46 samples.

How the data were processed

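The cells were hTERT-RPE-1, an established line of retinal pigment epithelial cells made permanent with telomerase, grown for 46 samples of 3 experiments. LINE-1 is a human retrotransposon, a DNA element that copies itself through an RNA intermediate, and it was expressed from an introduced construct. In the RNA sequencing, 3 libraries came from cells that expressed LINE-1 and 3 from cells that expressed luciferase, both from a doxycycline-inducible Tet-On system. In both knockout screens, cells with Cas9 were transduced with the Brunello library, in which single guide RNAs (sgRNAs) direct Cas9 to inactivate 1 gene per cell, and the sgRNAs in genomic DNA were sequenced. The first screen used cells with wild-type p53 transfected with a LINE-1 or an eGFP plasmid, 2 samples each at day 19. The second used cells with a p53 knockdown and Tet-On LINE-1 or luciferase, 3 cultures each, all sampled on days 4, 8, 13, 17, 22 and 27, which gives 36 samples. Per the labels, the replicates of the screens were biological. The labels do not say that the RNA libraries came from separate cultures, so p-values in the RNA-seq measure only the spread between these libraries, which may be technical.

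Per the submitters' processing notes, Bowtie, MAGeCK, STAR, HTSeq and DESeq2 and the genome build hg38 were used, with no versions, settings or annotation named in the sources used here. Per the file headers, the RNA table holds HTSeq read counts, and the deposited counts were whole numbers for 26485 gene symbols with a different total in each library. A stranded poly-A kit was used per the labels, but the strand setting of the counting was not given, so values of antisense genes, overlapping genes and close paralogs such as histone or interferon genes are uncertain. A table of the authors' own DESeq2 comparison gives log2 fold changes with standard errors, and the deposited adjusted p-values lie beside them. The authors also annotated p53 targets, DREAM targets and small gene sets in the RNA table. In the screens, the deposited signal per sgRNA is a read count multiplied by 1 factor per sample, set on non-targeting control sgRNAs. These controls cut no gene and stand for cells whose growth the library does not change.

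Whole reads were recovered from the steps between low screen values. In every screen sample 100% of low values lay within 0.1 read of a whole multiple of 1 step, but in luciferase culture 5 at day 13 of the knockdown screen that step could not be told from rounding. Spreadsheet software had turned 28 gene symbols of the RNA table and 26 of the knockdown screen (112 sgRNAs) into dates, and those genes were kept under the date name. Both screen tables hold part of the 76114 sgRNAs that the design text gives for the library. The wild-type table holds 15041 sgRNAs, only those above 0 in both eGFP samples, for 7853 genes, of which 3507 have 1 sgRNA and 342 have 4. The knockdown table holds 47264 sgRNAs for 11538 genes with 4 each and a set of 1000 controls. Of the genes in the knockdown table, 95.2% had a mean above 10 counts in the RNA table, against 54.9% of all genes there. For the wild-type table this share was 98.5%, and all of its 7853 genes are also in the knockdown table. Genes outside these tables were not analysed here.

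Depth sets the precision. RNA libraries held 43.6 to 67.3 M counts (M, 1e6). Recovered reads per sample were 29.8 to 38.0 M in the wild-type screen and 6.80 to 19.8 M in the knockdown screen. At day 27 of the knockdown screen, 1 read was worth 4.62 to 8.21 units in the LINE-1 samples and 0.694 to 0.765 in the luciferase samples. Reads of PCR products carry no molecular identifiers, so the 95% counting intervals and the floors given cover counting error only. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 6.39), and each was counted as a separate sample.

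RNA counts were tested with edgeR 4.0.16 in R 4.3.3 (low-count filter by expression, TMM factors, robust quasi-likelihood F-test, 2-sided), with Benjamini-Hochberg adjustment over 14645 genes and a call at an adjusted p below 0.05. Expression is given as counts per 1e6 (CPM), mean ± SD. A fold against a group with no counts was set against a floor of 3 counts per library, and with 1 to 3 counts the ratio of the pooled counts is given with an exact 95% interval.

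For the screens, a gene value was the mean over its sgRNAs of log2(deposited value + 5) in 1 sample, which understates changes at low values. An sgRNA needed a mean of at least 20 over all samples of its table and a gene at least 2 such sgRNAs, which left 3736 genes in the wild-type and 10938 in the knockdown screen. Gene values were tested with limma 3.58.1 (moderated with a trend, 2-sided), and the tables were never tested against each other because they were normalised separately. The main knockdown comparison took, in each of 6 cultures, the least-squares slope over the 6 days times the 23 days between the first and the last, and compared 3 LINE-1 with 3 luciferase cultures. Further comparisons were LINE-1 with luciferase at day 27, and day 27 with day 4 within each arm. Fits used no block. The culture numbers do pair the samples of an arm: deviations from the group means correlated at 0.528 to 0.543 between days 4 and 27 of the same LINE-1 culture and at 0.668 to 0.679 in the luciferase arm, against at most -0.242 for other pairs of cultures. A fit with the culture as a replicate block was an alternative.

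Effects are log2 differences ± SE unless another spread is named. On the deposited scale the effect of the median gene lay away from 0 in the knockdown screen, so effects there are given also relative to the median gene. A fit on values centred at each sample's median gene was added after seeing the data. The median of its effects over genes need not be 0. Groups of genes were tested with limma's camera (preset correlation 0.01, 2-sided, adjusted over the groups of 1 comparison) and again with an estimated correlation, and members called over all genes were counted beside those called when adjusted over the list alone. Comparisons, tests, 22 lists for RNA and 23 for the screens, the alternatives and the rule for named genes were fixed before the data were examined, but with knowledge of the published study, which reported on p53, Fanconi anaemia, HUSH and interferon genes, so those lists were not blind. Of these lists, 21, 19 and 22 had enough measured members in the RNA-seq, the wild-type and the knockdown screen.

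By the rule, named genes were the 10 highest and 10 lowest effects among called genes without overlap between the groups (for RNA a mean log2 CPM of at least 1, for screens at least 3 sgRNAs), in the screens the 5 with the smallest p in a direction where fewer than 5 passed, up to 3 members of each list with the smallest p, and CDKN1A in the screens. Some genes that the rule picked are not reported here. Other genes are said to be outside it where they are given. Alternatives were other scalings, filters, pseudocounts, gene summaries and tests (DESeq2 1.42.0, limma-voom, fry, edgeR on recovered reads), other treatments of days and blocks, and each replicate left out.

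The procedures were tested on simulated data with 200 changed genes. For the RNA-seq, 41.0%, 87.7% and 96.2% of changed genes were called at log2 changes of 0.5, 1 and 2 (14503 genes). In the RNA data themselves 9745 of 14645 genes were called, far more than were changed here, so these rates need not hold there. For the wild-type screen 0% were called even at a log2 change of 4 (3736 genes). For the knockdown slope 16.7% were called at 4, for day 27 8.97%, for the luciferase arm 3.13%, 46.1% and 85.0% at 1, 2 and 4, and for the LINE-1 arm 32.9% at 4 (10938 genes each). In the edgeR test on recovered reads, 0 genes were called in the wild-type screen, at day 27 or in the LINE-1 arm (55, 1622 and 1719 at an unadjusted p below 0.05), and 158 were called in the luciferase arm.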

Results

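RNA was sequenced from hTERT-RPE-1 cells induced to express LINE-1 or luciferase, with 3 libraries per group. The luciferase libraries A, B and C held 43.6, 67.3 and 46.2 M counts (M, 1e6), and the LINE-1 libraries F, G and H held 56.1, 55.9 and 52.7 M. Knockout screens asked which inactivated genes change the growth of cells that carry LINE-1. Cells with wild-type p53 gave 4 samples at day 19, with 29.8 to 38.0 M recovered reads each. Cells with a p53 knockdown gave 36 samples from 6 cultures over 27 days, with 6.80 to 19.8 M reads each. Neither the RNA nor the protein of the LINE-1 construct has a value in these tables.

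The RNA comparison asked what LINE-1 expression does to the transcriptome. Interferon-stimulated genes, which cells switch on when interferon or misplaced nucleic acid is sensed, rose in the LINE-1 libraries: 44 of 44 measured members were called higher, with a median log2 change of 3.57, or 3.07 with 3 members at 0 set to their bounds. OASL, an antiviral protein related to the oligoadenylate synthetases, went from 0.207 ± 0.0329 to 85.8 ± 13 CPM (log2 8.71 ± 0.19, n = 3 libraries per group as in all RNA values). OAS2, an oligoadenylate synthetase, rose by 7.92 ± 0.29, SAMD9, an antiviral restriction factor, by 7.0 ± 0.19, and IFI27 by 6.05 ± 0.17. MX2, which blocks viral nuclear entry, had 2 counts over all luciferase libraries and 2494 over all LINE-1 libraries, a ratio of 1201 (95% counting interval 332 to 9923), and the pro-apoptotic XAF1 had 2 and 781, a ratio of 376 (104 to 3111). IFNB1, which encodes interferon beta, had no counts in the luciferase libraries and 2.73 ± 0.534 CPM in the LINE-1 libraries, at least 40-fold higher. The type III interferons IFNL1 and IFNL3 were at least 6.03-fold and 3.83-fold higher, also from 0, and IFNA1, picked after its values were seen, rose by 1.92 ± 0.39. Of the 5 measured interferon ligands, 4 were called higher (list median log2 6.83 as fitted, 1.94 with bounds). Genes of antigen presentation rose, with 13 of 15 called higher, none lower and a median of 0.66, among them HLA-F (2.68 ± 0.11), the peptide transporter TAP1 (2.41 ± 0.11) and HLA-B (1.56 ± 0.09).

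Genes of NF-kB and inflammatory secretion rose in 20 of 21 measured members, with a median of 3.12. TNFAIP3, an inhibitor in the NF-kB pathway, went from 6.74 ± 0.460 to 294 ± 1.83 CPM (5.45 ± 0.08), and the cytokines IL1A and IL1B rose by 5.54 ± 0.10 and 3.73 ± 0.07. The 1 member called lower was TNFAIP2 (-0.65 ± 0.08), picked after its values were seen. Immediate early genes, the transcription factors made first after a stimulus, rose in 17 of 18 members, with EGR1 going from 15.8 ± 0.998 to 915 ± 0.203 CPM (5.85 ± 0.08) and KLF4 rising by 5.60 ± 0.10. Genes of the unfolded protein and integrated stress response rose in 17 of 22 members (median 1.65), led by the transcription factor ATF3 (6.11 ± 0.09), the glutathione-degrading CHAC1 (5.92 ± 0.10) and SESN2 (3.28 ± 0.08). PHGDH of serine synthesis fell by 0.62 and was the 1 member called lower, picked after its values were seen.

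Target genes of p53 rose in 31 of 35 members (32 adjusted over the list alone), with a median log2 change of 0.88. GDF15, a secreted stress cytokine, went from 0.111 ± 0.0221 to 39.6 ± 1.94 CPM (8.49 ± 0.14), the growth-arrest gene GADD45A from 38.1 ± 2.52 to 429 ± 21.3 CPM (3.5 ± 0.08), and the antiproliferative BTG2 rose by 3.67 ± 0.08. The members PLK2 and CYFIP2 were lower (-0.46 ± 0.06 and -0.49 ± 0.07). CDKN1A, the cell cycle inhibitor p21, rose by 2.47 ± 0.08, and MDM2, which degrades p53, by 1.49 ± 0.15. These 2 genes, PLK2 and CYFIP2 are outside the rule and were picked after their values were seen.

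Genes that copy and divide the genome moved down together. All 42 DNA replication genes fell (median -1.77), among them the helicase subunits MCM4 (276 ± 3.44 to 67.7 ± 0.578 CPM, log2 -2.03 ± 0.06) and MCM6 (-2.44 ± 0.07) and the sliding clamp PCNA (-1.84 ± 0.06). All 38 mitosis genes fell (median -2.12), with the mitotic kinesin KIF20A going from 224 ± 11.8 to 28.2 ± 0.929 CPM (-2.99 ± 0.07), the spindle protein PRC1 at -2.22 ± 0.06 and CENPF at -2.69 ± 0.08. Genes of the Fanconi anaemia pathway and homologous recombination, which repair crosslinks and broken replication forks, fell in 24 of 26 members (median -1.55), with FANCD2 at -2.55 ± 0.08, FANCI at -1.91 ± 0.07 and the nuclease EXO1 at -1.97 ± 0.08. Histone genes found in poly-A RNA rose in 6 of 10 members, including HIST1H2BC (4.62 ± 0.10) and HIST1H2AC (3.90 ± 0.09). The variants H2AFX and H2AFZ, picked after their values were seen, fell by 1.77 and by 1.83. Collagen and matrix genes were mixed, with 17 of 24 called higher and 6 lower (median 0.71), such as SPARC (1.83 ± 0.05), COL4A1 (1.20 ± 0.06) and COL12A1 (-1.37 ± 0.07).

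Lists with no shift as a group came next. Genes that restrict or silence LINE-1 were called higher in 8 and lower in 10 of 23 members (11 lower adjusted over the list alone), with a median of -0.16 and a mean of 0.06. They included the cytidine deaminase APOBEC3B at -2.40 ± 0.11, the membrane tether BST2 at 4.52 ± 0.21 and RNASEH2B at -1.52 ± 0.09. Heat shock genes were called higher in 5 of 12 (CRYAB 0.85 ± 0.09, DNAJB1, HSPB1, HSPA1B and BAG3) and lower in 4 (HSPE1 -0.95 ± 0.08, HSPD1 -0.62 ± 0.06, HSP90AA1 and HSPA8). Their median of 0.03 and mean of 0.01 were above 0 while the test pointed down. Cholesterol synthesis genes were called higher in 10 and lower in 2 of 19 (HMGCS1 0.96 ± 0.11, FDPS -0.88 ± 0.10). Markers of retinal pigment epithelium were called lower in 7 of 13 (8 adjusted over the list alone; PMEL -1.65 ± 0.17, OTX2 -0.78 ± 0.08, PAX6 -0.66 ± 0.07) and higher in 3, which were BEST1 (1.59 ± 0.17), MITF (0.88 ± 0.11) and RDH5 (0.54 ± 0.10). Endothelial markers were called higher in 5 of 8 and lower in 0 (median 1.27; TIE1 3.26 ± 0.15, to 9.44 ± 0.414 CPM, FLT1 3.17 ± 0.53, VWF 1.81, PECAM1 1.44 and TEK 1.10 ± 0.17). Leukocyte markers were called higher in 3 of 6 (LAPTM5 5.05 ± 0.41, PTPRC 0.63 ± 0.24, and ITGAM at least 7.49-fold higher from 0) and lower in 1 (CORO1A -1.82 ± 0.18). Fibroblast markers were called higher in 5 of 11 (DCN 1.48, COL3A1 1.41, ACTA2 1.15 ± 0.09, COL1A1 0.83 ± 0.08 and THY1) and lower in 3 (VIM -0.70 ± 0.05, TWIST1 and PDGFRB). Neural markers were called higher in 3 of 5 (SYP 1.30, TUBB3 1.22 ± 0.10 and MAP2) and lower in 1 (SNAP25 -0.76 ± 0.10). Keratinocyte markers were called higher in 1 of 5 (CLDN4 1.09 ± 0.19) and lower in 2 (KRT14 -2.33 ± 0.48 and KRT7 -0.57 ± 0.13). Of the genes in this paragraph, those past the 3 of each list with the smallest p were picked after their values were seen.

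Among all genes, the 10 highest changes also included those of FGF13, a fibroblast growth factor homologue (8.04 ± 0.21), the peptide hormone gene SPX (7.42 ± 0.27), the costimulatory receptor TNFRSF9 (6.85 ± 0.32) and the transcription factor EGR2 (6.65 ± 0.17). The lowest were NRK, a kinase, with 1194 counts in the luciferase and 3 in the LINE-1 libraries (ratio 413, interval 141 to 2007), and the transporter ABCA8 with 921 and 3 (ratio 319, interval 109 to 1548). The MYC-network repressor MGA went from 14.0 ± 1.04 to 1.12 ± 0.0820 CPM (-3.64 ± 0.11) and carbonic anhydrase CA9 from 18.5 ± 3.62 to 1.5 ± 0.186 CPM (-3.61 ± 0.17). C16orf45 (-3.34 ± 0.13), the neuropeptide NMU (-3.05 ± 0.14), the fatty acid dehydrogenase ACADS (-2.95 ± 0.33), the kinase PKN3 (-2.86 ± 0.12) and KIAA1644 (-2.83 ± 0.11) were also among the lowest.

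In edgeR's quasi-likelihood test, 9745 of 14645 genes were called, 4906 higher and 4839 lower, with a median gene at -0.01. Its adjusted p was 4.51e-09 for GDF15, 2.33e-08 for KIF20A and 7.51e-08 for CDKN1A. By limma's camera, 12 of 21 lists shifted: interferon-stimulated genes (adjusted p = 8.5e-56), mitosis (9.4e-54), DNA replication (6.6e-42), NF-kB (2e-39), immediate early (4.9e-29), stress response (2.1e-19), Fanconi anaemia and recombination (1.2e-15), p53 targets (1.7e-14), histones (2.3e-06), antigen presentation (0.00015), collagen and matrix (0.0077) and interferon ligands (0.039). Of these, 7 held with an estimated correlation. The others did not: adjusted p = 0.058 with an estimated correlation for interferon-stimulated genes, and likewise adjusted p = 0.18 for interferon ligands, 0.18 for antigen presentation, 0.17 for histones and 0.13 for collagen and matrix. Adjusted p was 0.061 for endothelial markers, 0.37 for both retinal pigment epithelium and leukocyte markers and 0.44 to 0.81 for the other lists without a shift. The p53, interferon and Fanconi anaemia lists were drawn up with knowledge of the published study. The basis of the authors' own annotations is not given in the sources used here. They gave 195 of 306 p53 targets called higher and 51 lower, and 188 of 202 targets of the cell cycle repressor complex DREAM called lower and 8 higher. Their small gene sets gave 29 of 29 interferon genes and 44 of 48 p53 genes higher, and 77 of 78 DNA replication genes and 38 of 42 spindle genes lower. The authors' deposited table lists 9789 genes at an adjusted p below 0.05, and its log2 changes have Pearson's r = 0.9996 with those given here across 14642 genes, which are not independent replicates.

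**Figure D1:**
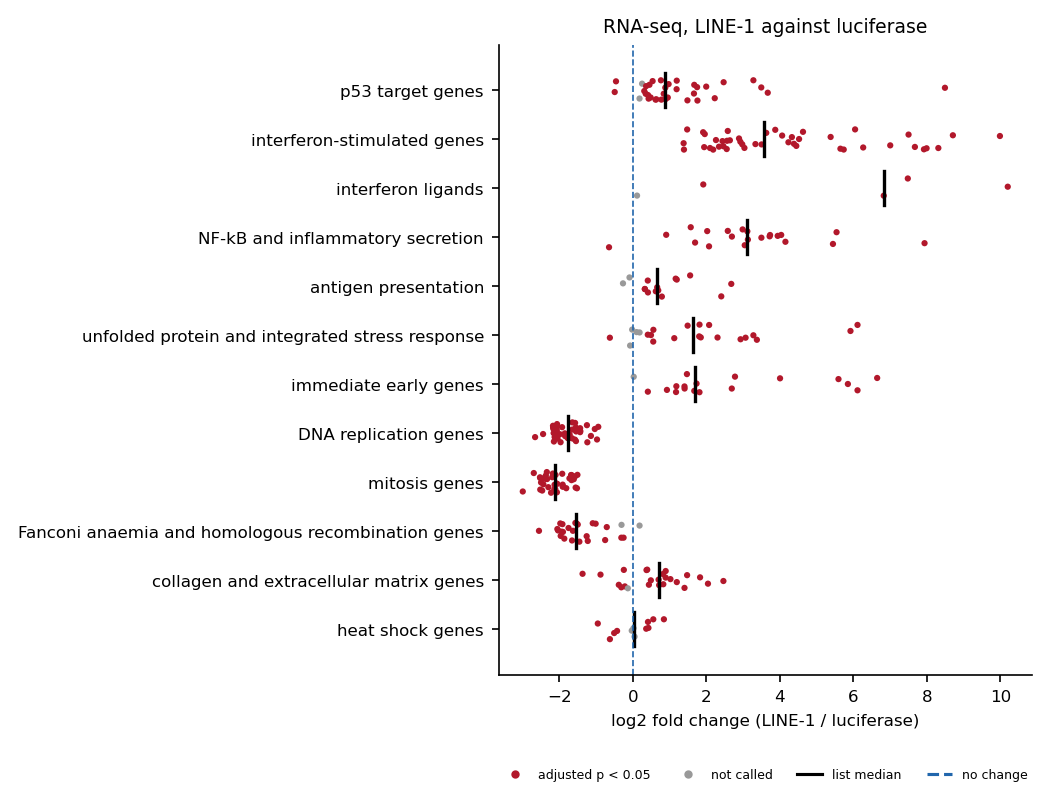
Log2 change of each measured gene (points, x axis; LINE-1 over luciferase, 3 libraries each) in 12 gene lists (y axis), red where called by edgeR and grey where not, with a black bar at the list median and a dashed line at 0. Interferon-stimulated genes (median 3.57) and NF-kB genes (3.12) lie to the right, mitosis (-2.12) and DNA replication genes (-1.77) to the left.

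The screen in cells with wild-type p53 asked which knockouts let cells grow with a LINE-1 plasmid, set against an eGFP plasmid at day 19. Knockouts of CDKN1A, which acts downstream of p53, had a mean gene value of 14.42 ± 1.19 in the eGFP and 16.23 ± 0.66 in the LINE-1 samples (log2 scale, SD, n = 2 each), a difference of 1.81 ± 2.29 that did not pass the test. The sgRNAs against CDKN1A held 0.714% and 3.72% of the eGFP samples and 2.49% and 5.69% of the LINE-1 samples. Of the 4 sgRNAs against it, 1 and 2 stood among the 100 most abundant in the eGFP samples and 2 and 3 in the LINE-1 samples. The sgRNAs disagreed. In LINE-1 sample B sgRNAs 3 and 4 lay above both eGFP samples, sgRNA 1 between them and sgRNA 2 below both (151 against 9333 and 597789). In sample D sgRNAs 1, 2 and 3 lay above both eGFP samples and sgRNA 4 below both (190 against 2198 and 1478).

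No other knockout passed either. The smallest p among higher knockouts belonged to C16orf74 (6.16 ± 2.31), NBEA, a membrane trafficking scaffold (7.13 ± 2.74), ZNF609 (6.51 ± 2.72), the sugar kinase NAGK (4.66 ± 2.02) and the mitochondrial NLRX1 (6.32 ± 2.79). Among lower knockouts it belonged to RAPGEF1, an exchange factor for RAP1 (-8.13 ± 2.2), the ciliary TMEM17 (-6.21 ± 2.01), JRK (-5.81 ± 1.98), EVI2B (-5.32 ± 1.87) and the receptor NOTCH1 (-5.98 ± 2.24). In limma, 0 of 3736 genes were called, with 85 at an unadjusted p below 0.05 (CDKN1A adjusted p = 1). edgeR on recovered reads and fry over sgRNAs also called 0, with 55 and 145 at an unadjusted p below 0.05. No list shifted by camera (19 lists, adjusted p = 0.99 for each, 0 at an unadjusted p below 0.05), and the median gene lay at -0.23. The LINE-1 samples were coarser: 1 read was worth 1.76 to 2.61 units there and 0.459 to 0.530 in the eGFP samples, and 29.7% to 36.1% of sgRNAs had 0 reads. The table holds only sgRNAs above 0 in both eGFP samples, so zeros are absent from the eGFP samples by that selection, and the share at 0 and the median gene are not free of it.

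**Figure D2:**
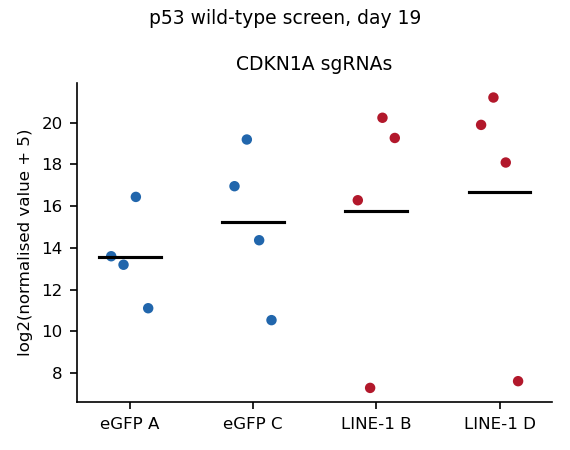
Normalised value of each of the 4 sgRNAs (points, y axis, log2 of value + 5) against CDKN1A in eGFP samples A and C and LINE-1 samples B and D (x axis) at day 19, with a black line at the mean. The mean over CDKN1A sgRNAs averaged 14.42 in the eGFP and 16.23 in the LINE-1 samples, a difference that did not pass the limma test.

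In the p53 knockdown screen, the luciferase arm shows which knockouts gain or lose ground without LINE-1 between days 4 and 27. Knockouts of APC, the scaffold of the complex that degrades beta-catenin, rose most, from 9.86 ± 0.14 to 16.03 ± 0.54 (6.17 ± 0.23, n = 3 cultures as in all values of this screen). Knockouts of KEAP1, which restrains the oxidative stress factor NRF2 (4.27 ± 0.25), and of the protein kinase A subunit PRKACA (4.06 ± 0.46) rose too. So did those of AXIN1 (3.57 ± 0.21), the G protein GNAS (3.37 ± 0.24), the beta-catenin inhibitor CTNNBIP1 (3.31 ± 0.43) and the cullin exchange factor CAND1 (3.29 ± 0.29). Growth-restraining tumour suppressors rose in 8 of 25 members (11 adjusted over the list alone; AMOTL2 2.26 ± 0.30), and 1, the kinase STK11, picked after its values were seen, fell by 2.79. Knockouts of mitochondrial gene expression fell: 59 of 75 mitochondrial ribosomal proteins (69 adjusted over the list alone; median -2.40 relative to the median gene), such as MRPS12 (-4.62 ± 0.48). Lower too were the helicase C10orf2 (-4.94 ± 0.47), the RNA polymerase POLRMT (-4.62 ± 0.48), the elongation factor GFM1 (-4.72 ± 0.50) and the threonine tRNA ligase TARS2 (-4.63 ± 0.45). The glycolytic TPI1 (-4.68 ± 0.43) and the hypusine enzyme DOHH (-4.81 ± 0.47) were also among the lowest. CDKN1A knockouts rose by 1.19 ± 0.23.

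Some knockouts of DNA repair genes fell in this arm. Mismatch repair had 0 of 8 called and base and nucleotide excision repair 2 of 20, both lower (3 adjusted over the list alone), and neither list shifted (adjusted p = 0.6 and 0.099). All 3 subunits of RNase H2, which removes ribonucleotides from DNA, were called lower (RNASEH2A -3.60 ± 0.45, RNASEH2C -2.50 ± 0.47, RNASEH2B -2.15 ± 0.44). Of 22 Fanconi anaemia genes 4 were called lower (16 adjusted over the list alone; list median relative to the median gene -1.14), namely FANCC (-2.38 ± 0.50), ERCC4 (-2.15 ± 0.55), UBE2T (-1.92 ± 0.42) and, picked after its values were seen, FANCI (-1.58 ± 0.40). Homologous recombination lost 7 of 27 knockouts (9 adjusted over the list alone; MRE11A -3.57 ± 0.45), end joining 4 of 16 (8; XRCC4 -3.10 ± 0.60, NHEJ1, LIG3 and, picked after, MAD2L2) and the ATR checkpoint 2 of 26 (5; CHTF8 -3.14 ± 0.53 and RAD1). DNA replication lost 3 of 25 (7; RFC2 -2.94 ± 0.58, POLE4 and ORC5) and cohesin and condensin 3 of 16 (8; SMC6 -2.97 ± 0.48, STAG2 and MAU2). The m6A and RNA processing factors lost 3 of 25 (6; WTAP -2.65 ± 0.44, METTL14 and EXOSC1) and the proteasome 3 of 14 (4; PSMD11 -2.53 ± 0.42, PSMD13 and PSMB3).

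In limma, 615 of 10938 genes were called in the luciferase arm, 48 higher and 567 lower, with the median gene at -0.32, and 459 with values centred at the median gene (85 higher, 374 lower). With the culture as a replicate block 1759 genes were called (147 higher, 1612 lower), among them all of the 615. By camera 12 of 22 lists shifted, of which mitochondrial ribosomal proteins (adjusted p = 5.9e-49), tumour suppressors (5.1e-19) and the Fanconi anaemia pathway (1.6e-06) held with an estimated correlation. Adjusted p was 2e-06 for homologous recombination, 5.7e-05 for RNase H2, 0.00095 for DNA replication, for cohesin and for m6A factors, 0.0021 for the ATR checkpoint, 0.0038 for end joining, 0.017 for the proteasome and 0.023 for p53 activators, whose 1 called member of 8 was CDKN1A. For these the call was lost, with adjusted p = 0.11 with an estimated correlation for homologous recombination, the proteasome and p53 activators, 0.09 for RNase H2 and 0.079 for the rest. The other lists had an adjusted p of 0.099 to 0.63. edgeR on recovered reads called 158 genes (60 higher, 98 lower), with the median gene at 0.09. With sgRNA means of at least 100, limma called 32 higher and 44 lower, so the excess of lower calls depends on the setting. Without day 4 of culture 4, 5 or 6 limma called 335, 289 and 275.

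The LINE-1 arm of the same screen asked the same between days 4 and 27 with LINE-1 expressed. APC knockouts rose from 10.02 ± 0.22 to 21.35 ± 0.95 (11.33 ± 0.48) and at day 27 held 60.3%, 44.1% and 44.0% of all normalised reads in the 3 cultures, against 9.85%, 4.14% and 8.85% in the luciferase cultures. Knockouts of SETD1B, a histone H3K4 methyltransferase (6.77 ± 0.51), of the SWI/SNF chromatin remodelling subunits SMARCD1 (6.58 ± 0.82) and BRD9 (5.05 ± 0.64), of the autophagy lipid scramblase ATG9A (5.65 ± 0.89) and of KEAP1 (5.20 ± 0.67) rose. TYK2 (3.68 ± 0.72) and JAK1 (2.81 ± 0.61), the kinases bound to the interferon receptor, rose as knockouts, as did the receptor IFNAR1 (3.32 ± 0.87), picked after its values were seen. They are 3 of 18 nucleic acid sensing and interferon signalling genes, of which 2 fell: ADAR, which edits double-stranded RNA (-3.92 ± 0.51), and ISG15, a ubiquitin-like protein that stabilises an inhibitor of interferon signalling (-3.17 ± 0.82, but 2.05 in edgeR on recovered reads; picked after its values were seen). The list median relative to the median gene was 1.73. Fanconi anaemia knockouts fell in 15 of 22 genes (20 adjusted over the list alone; relative median -1.62), with FANCI at -4.07 ± 0.50 and without reads in any LINE-1 sample at day 27. Homologous recombination knockouts fell in 11 of 27 (16 adjusted over the list alone; relative median -0.90; RAD50 -4.23 ± 0.60) and mitochondrial ribosomal proteins in 49 of 75 (67; relative median -1.90).

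Single knockouts that fell in the LINE-1 arm included the mitochondrial DNA packaging factor TFAM (-5.04 ± 0.61), the mitochondrial tRNA ligase IARS2 (-5.03 ± 0.56), RNASEH2A (-5.00 ± 0.56) and RNASEH2C (-3.41 ± 0.75). HUSH complex and H3K9 methylation genes, which silence retrotransposons, were called lower in 7 of 14 (9 adjusted over the list alone; relative median -1.51), among them MORC2 (-3.52 ± 0.47) and SETDB1 (-3.49 ± 0.64). Tumour suppressors had 1 of 25 knockouts called higher, KEAP1, and 2 lower, STK11 (-3.15 ± 0.68) and TAOK1 (-2.72 ± 0.65), with a list median of -0.42 and of 0.83 relative to the median gene. The p53 pathway had 2 of 21 called lower, the deubiquitinase USP7 (-4.82 ± 0.55) and AMBRA1, an adaptor that degrades D-type cyclins (-3.94 ± 0.61). CDKN1A knockouts stood at 0.19 ± 0.81 and did not pass the test.

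In limma, 1233 genes were called in the LINE-1 arm, 44 higher and 1189 lower, with the median gene at -1.26. With centred values 95 were called (48 higher, 47 lower; median gene at 0.18) and with equal sgRNA medians 91 higher and 0 lower. The median gene turned to 0.95 with equal sgRNA medians and 0.96 with edgeR on recovered reads. Without 1 day 4 sample, of culture 1, 2 or 3, limma called 512, 528 and 442 genes. Of those named as lower, IARS2, TFAM, RNASEH2A, FANCI and USP7 stayed below an adjusted p of 0.05 after centring (0.0216, 0.0297, 0.0227, 0.0422 and 0.0252). A replicate block for the culture gave 3379 calls (80 higher, 3299 lower), and edgeR on recovered reads 0, with 1719 at an unadjusted p below 0.05. By camera 11 of 22 lists shifted, and mitochondrial ribosomal proteins (adjusted p = 1.3e-20), sensing and interferon signalling (1.8e-08), Fanconi anaemia (1.1e-07), homologous recombination (2.7e-05) and tumour suppressors (0.00011) held with an estimated correlation. The calls of m6A and RNA processing factors (0.0012, 8 of 25 lower), end joining (0.0044, 6 of 16 lower), RNase H2 (0.018), the ATR checkpoint (0.024, 8 of 26 lower), 2 olfactory receptors (0.038, none called) and HUSH genes (0.048) were lost. With an estimated correlation the adjusted p = 0.071 for m6A factors, 0.14 for the ATR checkpoint and 0.16 for the others. With the replicate block the olfactory receptors had an adjusted p of 0.051, DNA replication went from 0.11 to 0.023 and cohesin from 0.068 to 0.019, both without a call with an estimated correlation (0.24 for each). The lists not given a value here had an adjusted p of 0.13 to 0.79.

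The comparison of slopes asked which knockouts fared differently with LINE-1 than with luciferase over the 23 days. Knockouts of MAP2K5 and MAPK7, the kinases MEK5 and ERK5 of 1 signalling cascade, both differed by 6.44, with SEs of 0.62 and 0.89. The fitted change of MAP2K5 was -2.14 ± 0.28 in the luciferase and 4.30 ± 0.33 in the LINE-1 cultures (SD, n = 3 cultures per arm). SETD1B knockouts (5.79 ± 0.57), the Mediator subunits MED24 (5.60 ± 0.75) and MED16 (4.35 ± 0.63), SMARCD1 (5.33 ± 0.74), and APC (5.31 ± 0.59) also rose relative to luciferase. The beta-catenin kinase CSNK1A1 (4.91 ± 0.67), the methyl-DNA reader ZBTB38 (4.41 ± 0.66) and the protease MBTPS1 (4.01 ± 0.69) rose as well. Knockouts of CAND1 went the other way, at 3.22 ± 0.17 in the luciferase and -2.47 ± 0.50 in the LINE-1 cultures (difference -5.69 ± 0.63), and those of the deubiquitinase OTUD5 differed by -5.55 ± 0.75. RALGAPB (-4.88 ± 0.97), the stress kinase MAPKAPK2 (-4.44 ± 0.68), the SUMO protease SENP1 (-4.41 ± 0.64) and the adaptor YWHAZ (-4.31 ± 0.65) all fell against the controls. So did ISG15 (-4.15 ± 0.87), HNRNPA1 (-4.10 ± 0.73), TAOK1 (-4.01 ± 0.63) and the zinc transporter SLC39A1 (-4.01 ± 0.64), and all 8 stood at 0.0629 to 0.209 (adjusted p) after centring, with effects of -3.72 (RALGAPB) to -2.85 (SLC39A1).

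Of 18 sensing and interferon signalling knockouts, TYK2 (3.95 ± 0.77) and JAK1 (3.01 ± 0.64) rose and ISG15 fell (7 higher and 2 lower adjusted over the list alone; median relative to the median gene 0.99). Of 22 Fanconi anaemia knockouts, 1 fell, UBE2T, the pathway's ubiquitin-conjugating enzyme (-2.67 ± 0.55; 9 lower adjusted over the list alone; relative median -0.75). FANCA (-2.86 ± 0.67) and FANCI (-2.51 ± 0.60) had adjusted p = 0.0519 and 0.0556 in limma. Among 14 HUSH and H3K9 methylation genes, TRIM28, a corepressor that silences retrotransposons, rose (3.33 ± 0.63), and 4 fell: SETDB1 (-3.58 ± 0.67), MORC2 (-3.48 ± 0.68) and, picked after their values were seen, MPHOSPH8 (-3.17 ± 0.65) and ATF7IP (-3.22 ± 0.73). Adjusted over the list alone, 2 were higher and 7 lower, and the list did not shift as a group (adjusted p = 0.6). Of m6A and RNA processing factors FTO (-3.08 ± 0.63), ZCCHC8 (-2.96 ± 0.61) and RBM7 (-3.23 ± 0.71) fell (3 of 25, 6 adjusted over the list alone), and of LINE-1 restriction genes ZC3HAV1 (-3.58 ± 0.76; 1 of 21). The p53 pathway had 1 of 21 called lower, AMBRA1 (-3.84 ± 0.60; 3 adjusted over the list alone), and mitochondrial ribosomal proteins 1 of 75, MRPS36 (-3.37 ± 0.71). CDKN1A knockouts stood at -0.91 ± 0.75 (adjusted p = 0.473, limma), and at 1.02 with equal sgRNA medians.

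**Figure D3:**
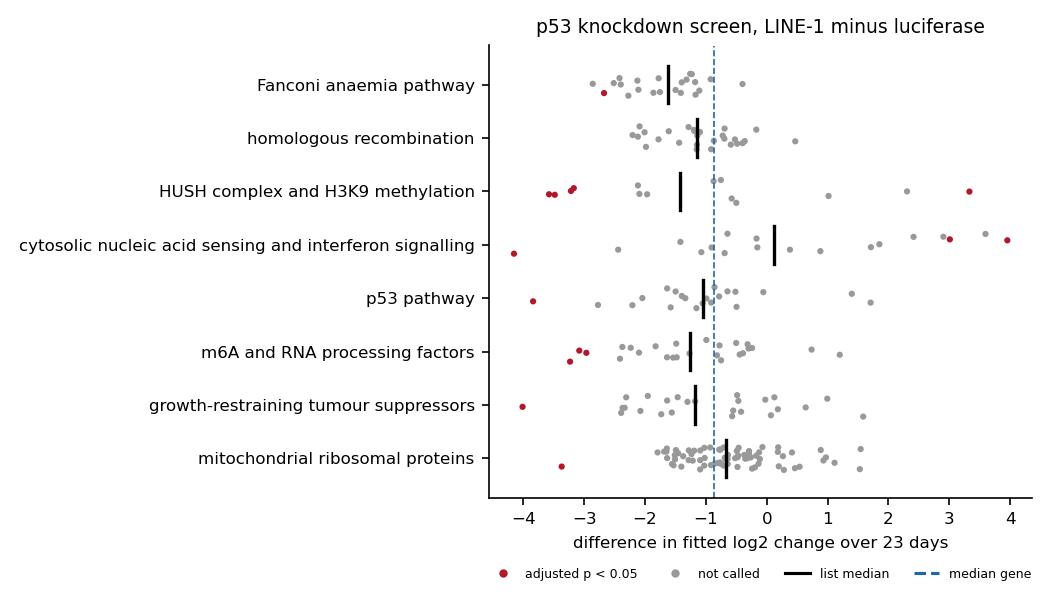
Difference between LINE-1 and luciferase cultures in the fitted log2 change over 23 days (x axis, 3 cultures per arm) for each gene (points) of 8 lists (y axis), red where called by limma and grey where not, with a black bar at the list median and a dashed line at the median gene (-0.87). Relative to that line the Fanconi anaemia median lies at -0.75 and the sensing and interferon signalling median at 0.99.

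**Figure D4:**
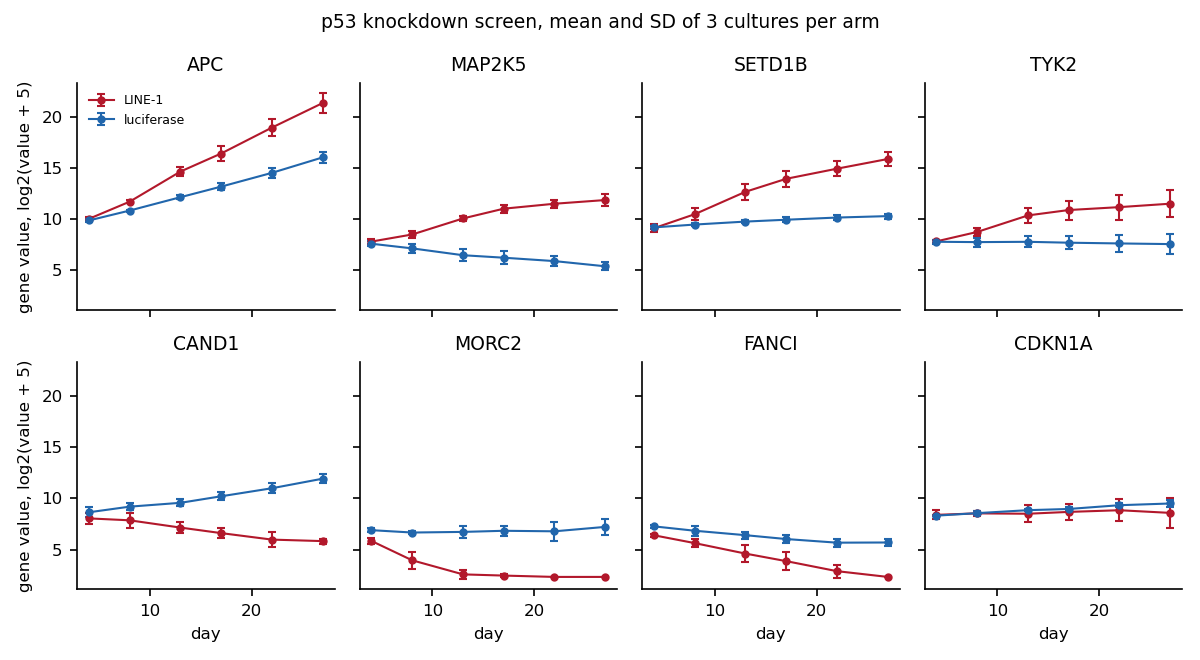
Gene value (y axis, mean over sgRNAs of log2 of value + 5) by day (x axis) for knockouts of 8 genes in LINE-1 (red) and luciferase (blue) cultures, as mean ± SD of 3 cultures. By day 27 APC stood at 21.35 with LINE-1 and 16.03 with luciferase, MAP2K5 at 11.85 and 5.37, and CAND1 at 5.82 and 11.93.

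In limma, 169 of 10938 genes differed in slope, 20 higher and 149 lower, with the median gene at -0.87 (adjusted p = 0.00104 for MAP2K5 and SETD1B, 0.0021 for APC and CAND1, 0.00996 for MAPK7 and OTUD5, 0.0336 to 0.0418 for TRIM28, TYK2 and JAK1, and 0.04 for UBE2T). With centred values 33 were called (31 higher, 2 lower), which kept the 20 higher ones and, of the lower ones, CAND1 and OTUD5. The median gene of the centred fit lay at 0.28, above 0, which favours higher calls. With equal sgRNA medians 337 were called higher and 2 lower, with the median gene at 1.05. UBE2T, SETDB1 and MORC2 had adjusted p = 0.335, 0.191 and 0.217 after centring, and lay at -1.80, -2.70 and -2.61 relative to the median gene. By camera 2 of 22 lists shifted, sensing and interferon signalling (adjusted p = 3.5e-06) and Fanconi anaemia (0.001), and both were lost, with adjusted p = 0.21 with an estimated correlation. On the scale of equal medians the Fanconi anaemia median turned from -1.63 to 0.30. That scaling moves all genes of a sample alike, so the distance from the median gene cannot change with it. The other lists had an adjusted p of 0.22 to 0.98. The sensing, Fanconi anaemia, HUSH and p53 lists were drawn up with knowledge of the published study. Without luciferase culture 4, 5 or 6 the calls dropped to 9, 3 and 5, and without LINE-1 culture 1 they numbered 406.

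At day 27 alone, MAP2K5 knockouts stood at 5.37 ± 0.39 in the luciferase and 11.85 ± 0.58 in the LINE-1 samples (6.48 ± 0.72) and SETD1B knockouts at 10.28 ± 0.25 and 15.87 ± 0.64 (5.59 ± 0.67). MED24 (5.41 ± 0.83), APC (5.32 ± 0.77), SMARCD1 (5.20 ± 0.87) and the histone chaperone SET (4.25 ± 0.79) rose. CAND1 (-6.11 ± 0.70), OTUD5 (-5.55 ± 0.90), CCDC97 (-5.29 ± 0.87), the RNA cap methyltransferase PCIF1 (-4.94 ± 0.78) and TAOK1 (-4.29 ± 0.73) fell. MORC2 (-4.89 ± 0.77) and SETDB1 (-4.64 ± 0.83) were the 2 of 14 HUSH genes called lower, and MORC2 sgRNAs had no reads in any LINE-1 sample. FANCI (-3.37 ± 0.65) was the 1 Fanconi anaemia gene called (10 of 22 lower adjusted over the list alone; relative median -0.98), FANCE being at -2.71 ± 0.74 (adjusted p = 0.079). None of the 18 sensing and interferon signalling genes was called (4 higher and 2 lower adjusted over the list alone; relative median 1.30), with TYK2 at 3.95 ± 0.83 (adjusted p = 0.059). AMBRA1 (-4.23 ± 0.83) and RBM7 (-3.90 ± 0.77) were the called members of the p53 pathway and of the m6A factors. CDKN1A knockouts stood at -0.92 ± 0.82 (adjusted p = 0.512), and at 1.11 after rescaling to equal sgRNA medians.

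In limma 39 genes were called at day 27, 9 higher and 30 lower, with the median gene at -1.03. With centred values 31 were called (30 higher, 1 lower, CAND1), with the median gene at 0.23. With equal medians 149 were called (148 higher, 1 lower). The median gene turned to 0.997 with equal medians and 0.93 with edgeR on recovered reads. All 9 higher and 22 of the 30 lower genes were also called by slope. Camera called the same 2 lists, Fanconi anaemia (adjusted p = 8e-04, and adjusted p = 0.26 with an estimated correlation) and sensing and interferon signalling (2.2e-05, and adjusted p = 0.27 with an estimated correlation), and the others had 0.099 to 0.94. The Fanconi anaemia median was -2.01, and 0.02 with equal medians. Without luciferase culture 4, 5 or 6 limma called 0 genes (1501, 1498 and 1550 at an unadjusted p below 0.05), and edgeR on recovered reads called 0 with all samples (1622).

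Representation of the library differed between the arms of the knockdown screen. At day 4, 1.80% to 2.70% of sgRNAs had 0 reads in the LINE-1 cultures and 1.25% to 1.67% in the luciferase cultures. At day 27 these shares were 38.0% to 43.7% and 10.8% to 11.5%. The 10 most abundant sgRNAs then held 56.7% to 76.1% of the LINE-1 and 6.20% to 16.9% of the luciferase reads. The SD of log2 values over non-targeting sgRNAs was 2.67 to 2.96 with LINE-1 and 1.18 to 1.23 with luciferase.

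**Figure D5:**
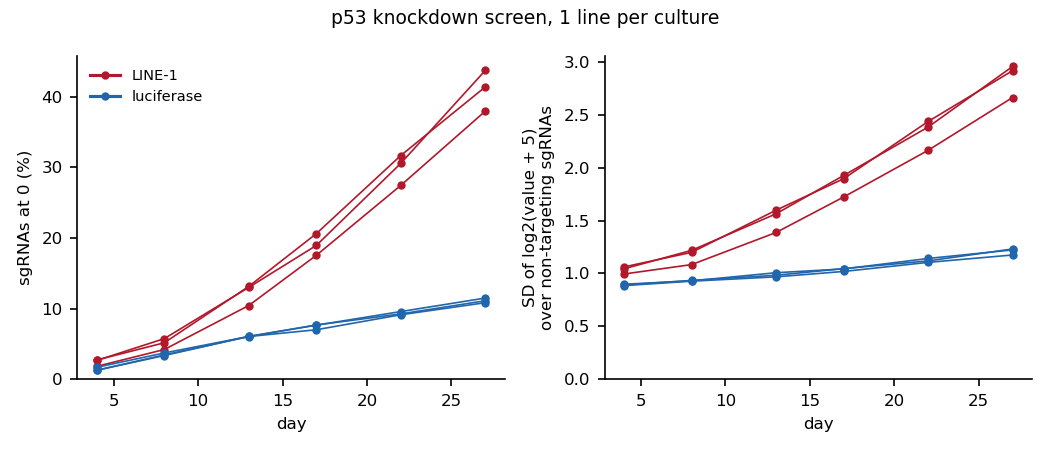
Percent of sgRNAs with 0 reads (left y axis) and SD over non-targeting sgRNAs of log2 of value + 5 (right panel, y axis) by day (x axis), with 1 line per culture, red for LINE-1 and blue for luciferase. At day 27 the LINE-1 cultures had 38.0% to 43.7% of sgRNAs at 0 and the luciferase cultures 10.8% to 11.5%.

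Effects of LINE-1 on knockouts were compared between the screens across 3730 genes measured in both. Pearson's r was 0.0273 and Spearman's rho 0.0332 between day 19 with wild-type p53 and day 27 with the knockdown, and r was 0.0269 with the slope, which describes genes that are not independent replicates. Differences between the screens were not tested for single genes because the tables were normalised separately. Noise lowers such correlations, and in the wild-type screen 0% of simulated changes were called even at a log2 change of 4. The screens also differ in how LINE-1 was delivered, in the control and in the day. These correlations therefore cannot show whether effects of LINE-1 depend on p53.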

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

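Of the tests here, the thinning of reads for the median gene, the pairing of A with B and C with D, and the centring at the median gene were chosen only after the result was seen. In the tests of causes, ± is an SD over 1000 bootstrap draws of genes, or of control sgRNAs in the test of drift. That SD holds no spread between cultures.

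Knockouts of 3 of 17 named genes measured in both screens moved one way in every LINE-1 sample with wild-type p53 and the other way in every LINE-1 sample at day 27 of the knockdown screen. NAGK stood at 4.66 and -1.65, SMARCD1 at -5.06 and 5.20, and ZMYM2 at 1.43 and -4.56 (SMARCD1 and ZMYM2 in the wild-type screen and NAGK in the knockdown screen were picked after their values were seen). NAGK turned to 0.37 at day 27 with equal sgRNA medians and to 0.63 with edgeR on recovered reads, the direction of the wild-type screen. These differences between the screens were not tested. Groups without overlap arise by chance in 33.3% of comparisons of 2 against 2 and 10% of 3 against 3, rates that do not hold in the screen where a gene was picked for its lack of overlap or small p. Separately, the non-targeting sgRNAs, which enter no comparison of genes, spread out over time: the SD of their log2 change from day 4 to day 27 was 1.41 in the LINE-1 arm and 0.406 in the luciferase arm.

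The median gene lay at -1.03 in the LINE-1 samples at day 27, relative to luciferase, at -1.68 with a pseudocount of 1 and at -0.52 with 20. It lay at 0.997 with equal sgRNA medians and at 0.93 with edgeR on recovered reads. The edgeR fit kept the scale of the non-targeting controls but summed reads over sgRNAs. The sign of the median gene thus rests on the scaling and on the gene summary. With the main scale and summary, coarser depth (fewer reads per sgRNA) as the cause needs the median gene to return to 0 with thinned reads. Thinning made 1 read worth the same in all 6 samples, but the median gene stayed at -0.984 ± 0.0129. For a larger loss of knockouts that already cost fitness, genes were classed by luciferase culture 4. The 3467 genes that did not fall there had a median of -1.01 ± 0.0193 against the other luciferase cultures. The 7471 other genes had a median of -1.02. These values show no loss tied to that class. However, 1 culture set the classes and low values understate a further fall, so this cause is not excluded. Drift of sgRNAs that start at a low level remains a candidate explanation, tested only at levels that held enough controls. There targeting sgRNAs lay at -0.676 and non-targeting ones of the same day 4 level at -0.663, a difference of -0.0137 ± 0.196 (unmatched controls -0.206). That test covered the 50% of targeting sgRNAs in levels with at least 5 controls (7 in the lowest), whose shift was smaller than the mean of -1.03 over all. Controls started higher (median log2 value at day 4 of 8.81, against 7.21 for targeting sgRNAs), so levels short of controls lay at the low end. The test therefore cannot decide for sgRNAs that start low, and the larger shift of the rest stays open.

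Fanconi anaemia knockouts lay lower in the LINE-1 arm than the median gene, a call by camera that held with an estimated correlation within the arm (adjusted p = 0.037) but not against luciferase (0.21 by slope, 0.26 at day 27). The same list held in the luciferase arm too (0.034 by camera with an estimated correlation, relative median -1.14), so the call within the arm is not particular to LINE-1. Random lists were matched on start level and on the change in luciferase culture 4. Of these, 0.04% had a median slope as low as theirs of -1.66 against luciferase cultures 5 and 6. The matched median was -0.821 (range from -1.32 to -0.378 over 95% of lists). That argues against start level as the whole cause, though the draws hold no spread between cultures. Fitness cost was matched on culture 4 alone, whose noise can leave part of it unmatched, so it cannot be excluded. With thinned reads at day 27 the list median lay -0.632 ± 0.342 from the median gene, against -0.98 without thinning. That SD is over draws of the list's genes and was too wide to exclude coarser depth. A greater need for this pathway in cells with LINE-1 is a hypothesis that may hold and that depth and fitness cost keep open.

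Knockouts of nucleic acid sensing and interferon signalling genes lay higher than the median gene, which by camera held with an estimated correlation within the arm (adjusted p = 0.042) but not against luciferase (0.21 by slope, 0.27 at day 27). By slope 9 of 18 effects lay above 0. Again 0.04% of matched random lists had a median slope as high as theirs of 0.0711 against the same 2 cultures (matched median -0.772, from -1.28 to -0.263), which argues against start level and fitness cost. With thinned reads at day 27 the list lay 1.16 ± 0.684 above the median gene, against 1.30 without thinning. Most of the shift thus stayed at equal depth, but the spread over the list's genes was too wide to exclude coarser depth. The list also holds genes that restrain this signalling, such as ISG15, called lower by slope. A growth cost of interferon signalling in cells with LINE-1, which knockouts of kinases such as TYK2 and JAK1 would lift, may be a biological explanation. It has no test here beyond these.

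Other splits of the samples were refitted with the same tests. The 6 RNA libraries make 10 splits, too few for a share below 0.05: 1 split, the real one, called as many as 9745 genes and the highest other called 0. The same holds for the 10 splits of the 6 cultures, with 169 real calls by slope against 0 and 39 at day 27 against 1 in the highest other. In the luciferase and LINE-1 arms, whose cultures are paired, 4 splits part all 3 pairs, also too few, with 615 against 0 and 1233 against 0.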

How the results depend on the processing

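Centring at the median gene, the pairing of samples in the wild-type screen, thinned reads for the day 27 calls and the median gene, and blocked list tests were chosen after seeing the data. The RNA-seq calls stayed within 1.5 times of 9745 under every scaling, filter and tool, and from 8535 (without LINE-1 library G) to 10782 (without luciferase library C) with 1 library left out. Of 1299 values of its 109 named genes under alternatives, none changed direction. The wild-type screen gave 0 calls in every setting but 1, the pairing of A with B and C with D (the deviations of these samples went together), which called 1 gene, lower; no replicate left out gave a call (0 to 0 by limma, 47 to 175 at an unadjusted p below 0.05).

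The knockdown screen's counts depend on the processing, and the cause was not tested unless stated. Slope calls (169) became 675 with a pseudocount of 1, 54 with 20, 377 without a filter on low sgRNAs and 12 with sgRNA means of at least 100. They became 339 with equal sgRNA medians, 725 with the median over sgRNAs, 40 without day 4 and 33 with centred values. They became 1980 with 36 samples in 1 fit and no replicate block, which treats days as replicates. Without 1 culture they ranged from 3 (without luciferase 5; 9 and 5 without 4 and 6) to 406 (without LINE-1 1). Day 27 calls (39) became 421 and 16 with pseudocounts of 1 and 20, 2 without the filter, 4 with means of at least 100, 149 with equal medians, 630 with the median over sgRNAs, and 81 with fry. They became 0 with edgeR on recovered reads (1622 at an unadjusted p below 0.05). They ranged from 0 (without any 1 luciferase culture; 1498 to 1550 at an unadjusted p below 0.05) to 35 (without LINE-1 2; 11 and 5 without 1 and 3). Thinned reads gave 28.

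Luciferase arm calls (615) became 1382 without the filter, 76 with means of at least 100, 158 with edgeR and 1759 with the replicate block for the culture. They ranged from 275 (without day 4 of culture 6; 335 and 289 without 4 and 5) to 658. LINE-1 arm calls (1233) became 2198 and 668 with pseudocounts of 1 and 20, 2371 without the filter and 12 with means of at least 100. They became 91 with equal medians, 1869 with the median over sgRNAs, 0 with edgeR (1719 at an unadjusted p below 0.05), 95 with centred values and 3379 with the replicate block. They ranged from 442 (without day 4 of culture 3; 512 and 528 without 1 and 2) to 1711. In lists, 15 of 39 calls held with an estimated correlation, among them 3 of 12 in the luciferase and 5 of 11 in the LINE-1 arm. For lists fixed beforehand the block changed no call in the arms but those of olfactory receptors, DNA replication and cohesin. Correlations between the screens over genes called in either were -0.260 (13 genes, day 27) and -0.117 (60 genes, slope).

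The sign turned for CDKN1A, which passed no test there. With equal medians it stood at 1.02 by slope and 1.11 at day 27, and with edgeR on recovered reads at 0.40 at day 27. With centred values it stood at 0.24 by slope, below the median gene of that fit (0.28), and at 0.34 at day 27 (median gene 0.23). In the LINE-1 arm ISG15 turned to 2.05 with edgeR on recovered reads. CDKN1A there stood at -0.06 without day 4 of culture 1, at -0.61 without day 27 of culture 3 and at 0.87 without day 27 of culture 2. At day 27 NAGK, which passed no test, turned to 0.37 with equal medians and 0.63 with edgeR. Other named genes kept their direction. Reads per sgRNA limit the LINE-1 samples most, with a median of 3 to 6 at day 27 against 165 to 182 with luciferase. Their recovered reads were not fewer (17.4 to 19.8 M against 15.5 to 16.4 M), but the 10 most abundant sgRNAs held 56.7% to 76.1% of them.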

Other observations

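The gene groups here were chosen after the data were seen, as were their tests, and are given as values.

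In the RNA-seq, genes of EGF receptor ligands and MAP kinase feedback rose in 12 of 14 members (median log2 change 1.57, camera adjusted p = 1.9e-10, 0.011 with an estimated correlation), such as the ligands AREG (3.37 ± 0.09) and HBEGF (37.8 ± 2.5 to 224 ± 7.22 CPM, 2.56 ± 0.07). Cytosolic ribosomal proteins were called lower in 82 of 84 genes (median -0.91, RPLP0 -1.39 ± 0.09; adjusted p = 3e-13, and adjusted p = 0.52 with an estimated correlation) and oxidative phosphorylation genes in 58 of 71 (median -0.53, NDUFB6 -0.88 ± 0.08; 1.6e-05, and adjusted p = 0.55 with an estimated correlation). Autophagy and lysosome genes were called higher in 9 and lower in 2 of 14 (0.0014, and adjusted p = 0.33 with an estimated correlation). Hypoxia response genes did not shift (8 higher and 5 lower of 19, adjusted p = 0.24), with ANGPTL4 at 3.18 ± 0.12 and CA9 at -3.61 ± 0.17.

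In the p53 knockdown screen by slope, the 4 kinases of the MEK5 and ERK5 cascade lay highest of the groups, with a median of 4.84 relative to the median gene (adjusted p = 2.6e-12, 0.016 with an estimated correlation). MAP2K5 and MAPK7 were called. In the luciferase arm the knockouts of MAP2K5 (-2.21 ± 0.42) and MAPK7 (-2.44 ± 0.49) were called lower. Knockouts of the Mediator complex, which links activators to RNA polymerase II (4 of 20 called higher, 5 higher and 3 lower adjusted over the list alone, 10 of 20 effects above 0, MED24 5.60 ± 0.75; 0.017 with an estimated correlation), of SWI/SNF remodellers (4 of 27, 6 higher and 2 lower adjusted over the list alone, 12 of 27 effects above 0, SMARCD1 5.33 ± 0.74 and BRD9 3.88 ± 0.62; 0.017), of SET1 methyltransferase complexes (1 of 12, SETD1B; 1 higher and 1 lower adjusted over the list alone; 0.03) and of the beta-catenin destruction complex (2 of 7, APC and CSNK1A1; 0.017) also lay higher than other genes by slope. Other comparisons differed: the median relative to the median gene was -1.38 for SWI/SNF in the wild-type screen (camera adjusted p = 0.2). In the luciferase arm SWI/SNF knockouts also lay higher, with a relative median of 0.59 and 2 of 27 called higher and 2 lower. The camera adjusted p there was 2.7e-06, and 0.021 with an estimated correlation. For the Mediator complex this relative median was -0.68 in the LINE-1 arm and -0.51 in the luciferase arm. For SET1 complexes it was -0.09 in the LINE-1 arm. SET1 complexes had 5 of 12 called lower in the luciferase arm (camera adjusted p = 0.0099, and adjusted p = 0.069 with an estimated correlation). Regulators of cullin-RING ligases and neddylation lay lower (1 of 17 called, CAND1; 10 adjusted over the list alone; 0.03 with an estimated correlation). In the luciferase arm this group did not shift (adjusted p = 0.077), but did with the culture as a replicate block (0.039). These groups were picked because some of their members had been seen to change, so their tests are not independent. Knockouts of autophagy genes (adjusted p = 0.061) and of mitochondrial tRNA ligases (0.72) did not differ between the arms by this test. At day 27 the median of the tRNA ligases relative to the median gene depended on the tool, at 0.40 in limma and -3.02 with edgeR on recovered reads. The tRNA ligases were called lower in 15 of 16 in both arms, such as IARS2 at -4.41 ± 0.45 in the luciferase and -5.03 ± 0.56 in the LINE-1 arm. The beta-catenin complex was called higher in 4 of 7 in both.

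APC knockouts ranked first in their share of reads in each of the 36 samples of this screen.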
